A study of Macaca mulatta with 102 samples.

How the data were processed

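RNA of CD3-positive T cells, sorted from macaque blood by flow cytometry, was measured on Affymetrix rhesus arrays prepared from 70 to 85 ng of total RNA with a kit that labels from the 3' end. The deposited values are log2 RMA signal intensities, per the labels, made by the authors with RMA in the affy package, whose versions the labels do not give. The table holds 52865 probe sets in 102 arrays. Array medians ran from 5.13 to 5.35 and array maxima from 14.7 to 16.9. In healthy controls 0.225% of probe sets had a batch F p under 0.05 and 29.8% one above 0.95, where 5% each are expected by chance, and 4.42% were under 0.05 with the batch labels shuffled once, so the values appear to have been adjusted for batch before deposition.

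Gene names were taken from the platform annotation, which pairs 24969 probe sets with a single gene, 361 with several and 27535 with none. Of the single-gene probe sets 24629 had an identifier in the RefSeq gene table of assembly T2T-MMU8v2.0, which changed 0 symbols, and no coordinates were used. PRF1, IL7R and CD3E have no single-gene probe set. Probe sets of immunoglobulin, T cell receptor, MHC and KIR genes can cross-hybridize and are not named. The arrays of healthy animal R.201, measured on 2 arrays, were averaged, which left 101 arrays. Probe sets were kept when their value reached the median of all values (5.21) in at least 3 arrays. After 99 control probe sets were left out, 31711 remained. A gene was represented by its single-gene probe set with the highest mean, which gave 10718 genes.

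Differences were estimated with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8. All 16 groups were fitted together with the labelled batch (6 batches) as a factor, with empirical Bayes moderation (80 residual and 3.38 prior degrees of freedom), and p values were adjusted by the Benjamini-Hochberg method over the 31711 probe sets at a threshold of 0.05. The KY1005 groups lie in a single batch that holds 7 healthy arrays. The 15 main comparisons set groups against healthy controls or against each other, 15 other comparisons were made as counts and list shifts, and the difference of the time courses was tested as an interaction. Animals recur between groups, and the residuals of arrays of the same animal had a median correlation of 0.184 over 51 pairs. The animal was therefore also fitted as a random block (consensus correlation 0.11). For KY1005.Siro.F against KY1005.Siro.D14 it was also fitted as a fixed block, on the KY1005.Siro arrays alone.

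A total of 26 gene lists, 16 of programmes, 2 of handling and 8 of cell types, were tested with camera of limma with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. They are cell cycle, cytotoxic effector, naive and central memory, regulatory T cell, costimulation and checkpoint, OX40 and NF-kB signalling, Th1, Th2, Th17, interferon response, glycolysis, sterol and lipid synthesis, mTORC1 targets, oxidative phosphorylation, tissue homing, apoptosis, immediate early, heat shock, core T cell, B cell, monocyte and myeloid, NK cell, neutrophil and granulocyte, erythroid, platelet and plasma cell. Genes were named by a rule: the 8 largest rises and the 8 largest falls past the threshold, up to 4 members past the threshold of each list described, and a fixed set (TNFRSF4, FOXP3, MKI67, GZMB, PRF1, IFNG, CCR7, IL7R, CD3E, CD4 and CD8A). The groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

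Alternatives were no batch term, the animal as a block, only the groups compared, only batches that hold the group, other filters, a trended robust prior, array weights, a further quantile normalization, a 2-fold minimum, leaving out each array in turn, leaving out the repeat array of R.201, pooling the 4 KY1005-only animals, and the mean of all probe sets of a gene. Those added after the data were seen left out the 6 arrays with a log2 ratio of 3' to 5' actin control probe sets above 2.5, the same within batches, or added that ratio or the myeloid score as a covariate. The fit was tested on simulated data with 200 changed probe sets among 31711, beside a shifted cell cycle list. It recovered 89% of 2-fold and 99% of 4-fold changes for NoRx.F against healthy controls, 82% and 96% for KY1005.F, 84% and 98% for KY1005.Siro.D14, and 51% and 92% for KY1005.Siro.D14 against Auto.D14. The simulated noise was independent between probe sets and arrays. It held no correlation between genes, animal effect or difference of RNA quality, so these rates do not cover them.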

Results

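Gene expression was measured on Affymetrix rhesus macaque arrays in CD3-positive T cells sorted from blood by flow cytometry. The 102 arrays covered 66 animals in 16 groups. Healthy untransplanted animals gave 46 arrays from 45 animals, and 56 arrays came from animals after a transplant of hematopoietic cells. Some animals, among them R.13, R.16, R.18, R.200, R.201 and R.202, gave both healthy arrays and arrays after transplant. The main fit did not pair them. Autologous recipients, which received their own cells, formed the groups Auto.D14, Auto.D36 and Auto.D100 with 3, 4 and 4 arrays. Recipients of donor cells had received no prophylaxis against graft-versus-host disease (NoRx.F, n = 4, days 6 to 12) or sirolimus, an inhibitor of mTOR (Siro.F, n = 4, days 12 to 24). Tacrolimus with methotrexate gave Tac.Mtx.D14 (n = 3) and Tac.Mtx.F (n = 3, days 26 to 67). Belatacept, a blocker of CD28 costimulation, with sirolimus gave Bela.Siro.D14, Bela.Siro.D30 and Bela.Siro.F with 3, 2 and 7 arrays, the last at days 26 to 105. KY1005, an antibody against OX40 ligand, was given alone (KY1005.D14, n = 2, days 14 to 16, and KY1005.F, n = 3, days 16 to 23). KY1005 with sirolimus gave KY1005.Siro.D14 (n = 5), KY1005.Siro.D28 (n = 5) and KY1005.Siro.F (n = 4, days 97 to 106). Names ending in F are used as the labels give them. The number of arrays limits the precision. Comparisons with healthy controls ask what a regimen leaves changed after transplant. Those between regimens ask how recipients of KY1005, alone or with sirolimus, differ. In several of these the day after transplant and the batch differ too. Values are log2 differences ± SE unless another error is named. They come from a fit with batch, so between groups that share no batch they can exceed the difference of the group means. The deposited values appear to have been adjusted for batch already, so this batch term is a second adjustment. Between groups that share no batch, differences and p values depend on it and are uncertain. Fits without a batch term are given below. In at least 1 comparison below, the lower mean of SERPINB2, TYMS, E2F8, MMP1, MMP8, MMP9, SOCS3, ORM1, MS4A1, CCL20, TPX2, IFNG, FOXP3 and JCHAIN lay under 5.21, the median of all values, where the size of a change is uncertain.

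**Figure D1:**
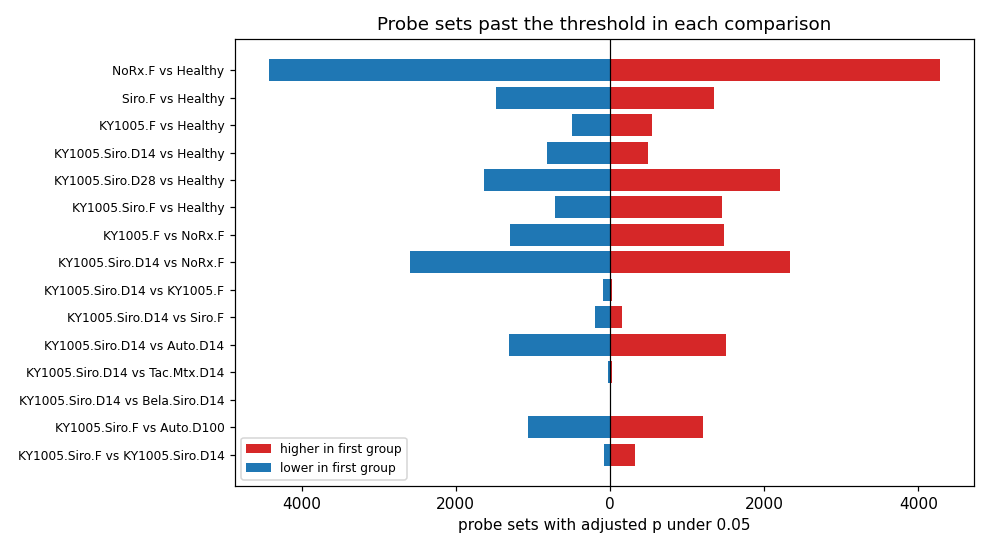
Number of probe sets with an adjusted p under 0.05 that were higher (right) or lower (left) in the first named group, for the 15 main comparisons. NoRx.F against healthy controls had the longest bars, with 4279 probe sets higher and 4426 lower, and KY1005.Siro.D14 against Bela.Siro.D14 the shortest, with 15 and 5.

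T cells of recipients without prophylaxis carried high levels of genes of cell division. CCNB2, a mitotic cyclin, rose by 4.70 ± 0.47, TYMS, which makes thymidylate for DNA synthesis, by 4.02 ± 0.50 and TOP2A, a DNA topoisomerase, by 3.64 ± 0.50 in 4 animals against 45 healthy controls. The inhibitory receptor LAG3 rose by 3.89 ± 0.35 and ENTPD1, an ectonucleotidase also called CD39, by 2.58 ± 0.28. Of 28 measured cell cycle genes 26 rose and 1 fell (26 and 2 adjusted over the list alone), with a median of 2.10 (adjusted p = 1.59e-19, and adjusted p = 0.149 with an estimated correlation). Among 15 genes of naive and central memory T cells 6 fell and none rose (7 fell adjusted over the list alone), among them the transcription factors KLF7 at -1.98 ± 0.28 and TCF7 at -1.50 ± 0.18 (list adjusted p = 0.00107, and adjusted p = 0.149 with an estimated correlation). Of 29 genes of oxidative phosphorylation 23 rose and 2 fell (24 and 2 adjusted over the list alone), as did 9 of 17 glycolytic genes (10 adjusted over the list alone), including LDHA at 1.33 ± 0.12. Both lists had adjusted p = 0.149 with an estimated correlation. Interferon-induced genes rose in 17 of 28 cases and fell in 1 (19 and 1 adjusted over the list alone), with IFI27 at 3.96 ± 0.56 and ISG15 at 2.61 ± 0.40, and this list had adjusted p = 0.49 with an estimated correlation. The granule genes GZMB and GNLY rose by 1.70 ± 0.36 and 2.09 ± 0.42. S100A9 and S100A8, the calprotectin subunits abundant in monocytes and neutrophils, rose by 4.73 ± 1.00 and 4.48 ± 0.97 beside these groups, as did the plasma cell gene MZB1 by 1.25 ± 0.17 and the B cell gene CD79B by 0.97 ± 0.21, while the NK cell gene KLRF1 fell by 2.79 ± 0.64. In all, 8705 of 31711 probe sets passed, 4279 higher and 4426 lower, or 49.2% higher, against 52% after a further quantile normalization. Within the batches that hold the group 6758 passed.

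Sirolimus-treated recipients showed a rise of the cell cycle genes as well. TOP2A rose by 2.44 ± 0.48, CCNB2 by 2.27 ± 0.45 and E2F8, a transcription factor of the cell cycle, by 2.03 ± 0.42 in 4 animals against 45. Of 28 cell cycle genes 22 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 1.09 (adjusted p = 1.26e-18, and adjusted p = 0.0457 with an estimated correlation). The OX40 gene TNFRSF4 rose by 1.22 ± 0.18 and the gene of its ligand, TNFSF4, by 1.21 ± 0.21. Of 16 genes of regulatory T cells 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00421 with an estimated correlation), with ENTPD1 at 2.23 ± 0.27, the inhibitory receptors CTLA4 at 1.57 ± 0.34 and TIGIT at 1.48 ± 0.24, while FOXP3, the factor that defines these cells, had a difference of 0.15 ± 0.13 (adjusted p = 0.565). Of 18 costimulation and checkpoint genes 6 rose (7 adjusted over the list alone; adjusted p = 0.0348 with an estimated correlation), LAG3 by 2.64 ± 0.34. Among naive and central memory genes 4 of 15 fell (5 adjusted over the list alone), with KLF3 at -1.51 ± 0.21 (list adjusted p = 0.00854, and adjusted p = 0.217 with an estimated correlation). Markers of other cells rose too, the plasma cell gene MZB1 by 1.05 ± 0.17 and the B cell gene CD79B by 0.73 ± 0.20. Of 7 plasma cell genes 2 rose (3 adjusted over the list alone; adjusted p = 0.0348 with an estimated correlation). The largest rise was that of SERPINE2, an inhibitor of serine proteases, at 3.27 ± 0.48. In all, 1345 probe sets were higher and 1479 lower, or 47.6% higher, against 53.5% after a further quantile normalization. The count of 2824 was 1614 within the batches that hold the group and 1016 without the array of R.18.

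With KY1005 alone, LAG3, CTLA4 and some of the cell cycle genes rose. LAG3 rose by 2.35 ± 0.41, CTLA4 by 1.77 ± 0.41, ENTPD1 by 1.61 ± 0.33 and TOP2A by 2.24 ± 0.58 in 3 animals against 45. SOCS2, a suppressor of cytokine signalling, rose by 2.72 ± 0.64. MMP8, a neutrophil collagenase, rose by 3.17 ± 0.49, S100A9 by 4.38 ± 1.17 and S100A8 by 4.35 ± 1.13. Of 8 granulocyte genes 1 rose (4 adjusted over the list alone; adjusted p = 0.00144, and adjusted p = 0.148 with an estimated correlation) and of 14 monocyte and myeloid genes 2 rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.00619, and adjusted p = 0.312 with an estimated correlation). Of 28 cell cycle genes 10 rose (20 adjusted over the list alone), with a median of 0.86 (adjusted p = 1.72e-14, and adjusted p = 0.111 with an estimated correlation). Of 28 interferon-induced genes 5 rose (7 adjusted over the list alone), with IFI27 at 2.55 ± 0.66 and MX1 at 1.93 ± 0.58 (list adjusted p = 3.25e-08, and adjusted p = 0.135 with an estimated correlation). Glycolytic genes rose in 3 of 17 cases (6 adjusted over the list alone), with LDHA at 0.69 ± 0.14 (adjusted p = 0.0488 with an estimated correlation), and the 13 apoptosis genes shifted up with 1 rise (7 adjusted over the list alone), that of TNFSF10, the death ligand TRAIL, at 1.43 ± 0.44 (adjusted p = 0.0127 with an estimated correlation). PF4, a platelet chemokine, fell by 3.35 ± 0.98 and the B cell gene MS4A1 by 2.12 ± 0.61. TNFRSF4 differed by 0.15 ± 0.23 (adjusted p = 0.727). In all, 544 probe sets were higher and 496 lower, or 52.3% higher, against 34.4% after a further quantile normalization. The count of 1040 was 6 within the batch that holds the group, 145 without the 6 arrays of high actin ratio described for RNA quality, 41 without the array of R.211 and 202 without that of R.206. It was higher with array weights, without a batch term and with the 4 KY1005-only animals pooled, as given below.

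At day 14 of KY1005 with sirolimus, SERPINB2, an inhibitor of plasminogen activators, rose by 3.92 ± 0.55 from a low healthy mean of 3.29, PGAP1, an enzyme that processes GPI anchors, by 3.09 ± 0.36, SOCS2 by 2.86 ± 0.54 and the cytokine gene IL1B by 2.57 ± 0.53 in 5 animals against 45. SMAD7, an inhibitor of TGF-beta signalling, fell by 1.76 ± 0.35, MS4A1 by 1.76 ± 0.52, PF4 by 2.80 ± 0.83 and the plasma cell gene JCHAIN by 1.27 ± 0.37. Of 14 monocyte and myeloid genes 3 rose (9 adjusted over the list alone), S100A9 by 3.55 ± 0.99, S100A8 by 3.53 ± 0.96 and FCN1, a monocyte lectin, by 2.72 ± 0.79 (list adjusted p = 1.62e-06, and adjusted p = 0.192 with an estimated correlation). The myeloid scores of the arrays were 2.36 (R.217), 1.16 (R.218), 0.94 (R.219), 1.52 (R.220) and 1.30 (R.221), where healthy scores had an SD of 0.51. RNA of other cells therefore stays open as a source of the rises of SERPINB2 and IL1B. Interferon-induced genes rose in 2 of 28 cases and fell in 1 (5 and 1 adjusted over the list alone), with IFI27 at 2.28 ± 0.56 and IRF7, a regulator of interferon genes, at -0.67 ± 0.14, or 0.12 as the mean of all its probe sets (list adjusted p = 0.000158, and adjusted p = 0.391 with an estimated correlation). Of 19 genes of OX40 and NF-kB signalling 2 rose (3 adjusted over the list alone), the survival gene BCL2 by 0.93 ± 0.19 and NFKBIE by 0.79 ± 0.18 (list adjusted p = 0.00402, and adjusted p = 0.192 with an estimated correlation). The cell cycle list was not called, and MKI67, a marker of proliferation, differed by 0.22 ± 0.37 (adjusted p = 0.804). In all, 499 probe sets were higher and 816 lower, 1315 together. The count was 53 within the batch, 427 with the myeloid score as a covariate, and 682, 673 and 658 without the arrays of R.217, R.219 and R.221.

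At day 28 of the combination SOCS2 rose by 3.40 ± 0.54, SOCS3, another suppressor of cytokine signalling, by 2.01 ± 0.28 and PGAP1 by 3.30 ± 0.36 in 5 animals against 45. SERPINB2 rose by 2.83 ± 0.55 and MMP1, a collagenase, by 2.70 ± 0.39. Of 19 genes of OX40 and NF-kB signalling 4 rose (7 rose and 1 fell adjusted over the list alone), the subunits NFKB2 by 1.84 ± 0.36, 1 of whose 3 probe sets passed in the other direction, and REL by 1.61 ± 0.44 among them (list adjusted p = 0.000516, and adjusted p = 0.0637 with an estimated correlation). Glycolytic genes rose in 5 of 17 cases (6 adjusted over the list alone), with PDK1, a kinase that limits pyruvate oxidation, at 1.28 ± 0.33 (list adjusted p = 0.000359, and adjusted p = 0.19 with an estimated correlation). The naive and central memory gene KLF7 rose by 1.03 ± 0.28, although its list was not called, and SATB1 differed by 1.15 ± 0.35, while another of its 4 probe sets passed in the other direction. CD40LG, the ligand of CD40, fell by 1.29 ± 0.23, GFI1, a transcriptional repressor, by 1.90 ± 0.43, and MS4A1 by 2.23 ± 0.52, with PF4 at -2.97 ± 0.83 and JCHAIN at -1.24 ± 0.37, the last 3 markers of B cells, platelets and plasma cells. MKI67 differed by -0.33 ± 0.37 (adjusted p = 0.621) and the cell cycle list was not called. In all, 2201 probe sets were higher and 1637 lower, or 57.3% higher, against 47.8% after a further quantile normalization. The count of 3838 was 620 within the batch, 725 without the 6 arrays of high actin ratio, 2350 with that ratio as a covariate, and 2338 and 1782 without the arrays of R.217 and R.221.

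Near day 100 of the combination interferon-induced genes and genes of myeloid and red cells rose together. IFIT1 rose by 3.36 ± 0.69, IFI44 by 2.89 ± 0.53 and MX1 by 2.79 ± 0.53 in 4 animals against 45, all 3 induced by interferon. Of 28 interferon-induced genes 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.80 (adjusted p = 5.04e-20, and adjusted p = 0.026 with an estimated correlation). Beside them 8 of 14 monocyte and myeloid genes rose (11 adjusted over the list alone), S100A9 by 4.41 ± 1.06 and VCAN by 3.57 ± 0.98, with a median of 2.11. Of 8 granulocyte genes 5 rose (5 adjusted over the list alone), MMP9 by 3.43 ± 0.50 and CAMP, an antimicrobial peptide, by 2.98 ± 0.69. Both lists had adjusted p = 0.028 with an estimated correlation. Of 8 erythroid genes 3 rose (5 adjusted over the list alone), the mitochondrial iron carrier SLC25A37 by 2.49 ± 0.37 and the heme enzyme ALAS2 by 1.97 ± 0.55 (list adjusted p = 2.01e-05, and adjusted p = 0.099 with an estimated correlation). Cytotoxic genes shifted down, with 1 rise and 2 falls among 22 (1 and 7 adjusted over the list alone), TBX21, the T-bet factor, at -1.83 ± 0.48 and GZMH at -1.76 ± 0.52 (list adjusted p = 0.0252, and adjusted p = 0.651 with an estimated correlation). SOCS2 rose by 3.81 ± 0.58 and CD8A fell by 0.64 ± 0.17. The myeloid scores of the arrays were -0.51 (R.217), 4.24 (R.219), 2.47 (R.220) and 2.23 (R.221). In all, 1452 probe sets were higher and 718 lower, or 66.9% higher, against 47.3% after a further quantile normalization. The count of 2170 was 16 within the batch, 756 without the 6 arrays of high actin ratio, 383 with the myeloid score as a covariate, and 3275, 483 and 1072 without the arrays of R.217, R.219 and R.220.

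**Figure D2:**
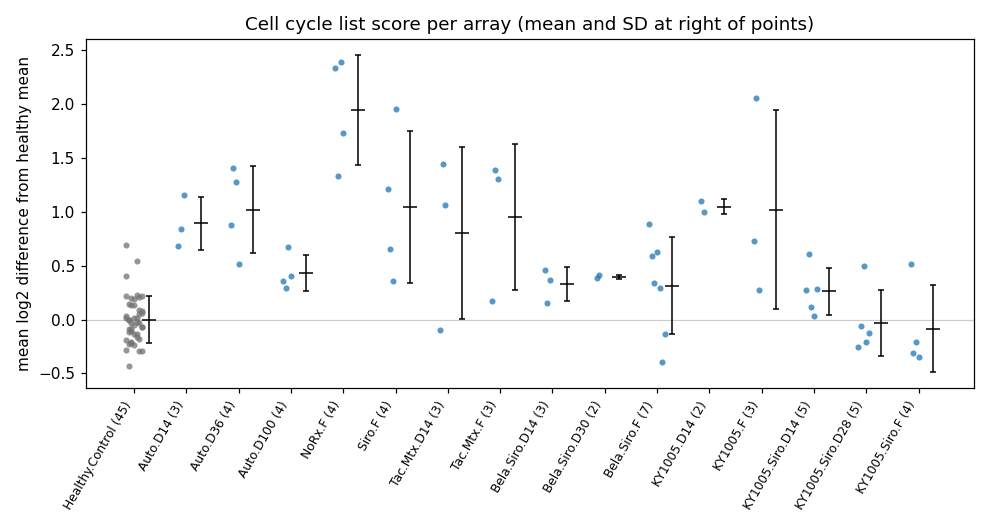
Cell cycle score of each array, the mean log2 difference of 28 genes from the healthy mean, by group with the number of arrays in brackets; points are arrays and the bars at their right are mean and SD. NoRx.F had a mean of 1.95 ± 0.51 (SD), KY1005.Siro.D14 0.26 ± 0.22 and KY1005.Siro.F -0.09 ± 0.40.

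**Figure D3:**
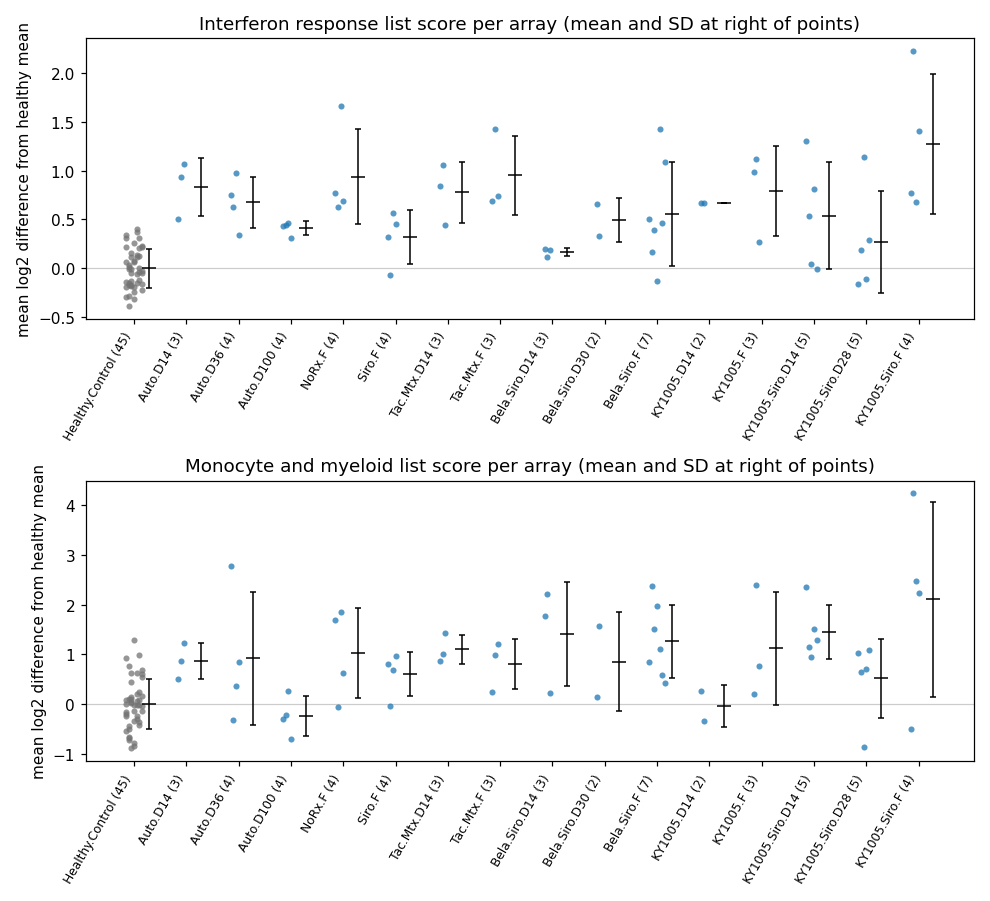
Interferon response score (28 genes) and monocyte and myeloid score (14 genes) of each array, as mean log2 difference from the healthy mean, with mean and SD at the right of the points. In KY1005.Siro.F the interferon scores ran from 0.67 to 2.23 and the myeloid scores from -0.51 to 4.24.

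Against recipients without prophylaxis, T cells under KY1005 alone had lower levels of division genes and higher levels of genes of resting T cells. CCNB2 fell by 2.92 ± 0.72, MCM4, a part of the replicative helicase, by 2.17 ± 0.38 and MKI67 by 1.86 ± 0.57 in 3 animals against 4. The naive T cell factors KLF7 and TCF7 rose by 1.98 ± 0.43 and 0.92 ± 0.28 and SOCS2 by 3.73 ± 0.84. Markers of other cells moved too: MMP8 rose by 3.03 ± 0.65 and KLRF1 by 2.87 ± 0.98, while MZB1 fell by 0.96 ± 0.27 and the B cell gene FCRLA by 0.77 ± 0.22. Of 28 cell cycle genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -1.15 (adjusted p = 8.05e-07). Of 15 naive and central memory genes 4 rose (8 adjusted over the list alone; adjusted p = 0.000137), and of 29 genes of oxidative phosphorylation 11 fell and 1 rose (16 and 1 adjusted over the list alone; adjusted p = 8.34e-05). With an estimated correlation these lists had adjusted p = 0.644, adjusted p = 0.177 and adjusted p = 0.644. Immediate early genes shifted up with 2 rises among 13 (5 adjusted over the list alone), JUNB by 1.79 ± 0.53 and MYC by 1.73 ± 0.49 (list adjusted p = 0.000259, and adjusted p = 0.644 with an estimated correlation). In all, 1482 probe sets were higher and 1290 lower, or 53.5% higher, against 39.6% after a further quantile normalization. The groups share no batch, and their days after transplant do not overlap, 16 to 23 against 6 to 12. Regimen, day and batch therefore cannot be told apart. The count of 2772 was 1212 without the 6 arrays of high actin ratio, and 1735 and 1087 without the KY1005.F arrays of R.206 and R.212.

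At day 14 of KY1005 with sirolimus, division genes were likewise lower and naive T cell genes higher than without prophylaxis. CCNB2 fell by 4.55 ± 0.66, with MKI67 at -3.08 ± 0.52, LAG3 at -3.12 ± 0.50, GZMB at -1.86 ± 0.51 and the chemokine receptor CXCR3 at -2.02 ± 0.31 in 5 animals against 4. KLF7 rose by 2.74 ± 0.39, SATB1 by 1.44 ± 0.49 (1 of its 4 probe sets passed in the other direction) and SOCS2 by 3.87 ± 0.77. The B and plasma cell genes MZB1, CD79B and FCRLA fell alongside, by 1.15 ± 0.24, 1.03 ± 0.30 and 0.60 ± 0.20. Of 28 cell cycle genes 24 fell and none rose (25 fell adjusted over the list alone), with a median of -1.92 (adjusted p = 1.23e-17, and adjusted p = 0.113 with an estimated correlation). Of 15 naive and central memory genes 6 rose (11 adjusted over the list alone; adjusted p = 4.74e-05, and adjusted p = 0.113 with an estimated correlation). Of 29 genes of oxidative phosphorylation 17 fell and 1 rose (20 and 2 adjusted over the list alone), with NDUFB3, a part of complex I, at -0.98 ± 0.19 (list adjusted p = 5.76e-06, and adjusted p = 0.411 with an estimated correlation). In all, 2339 probe sets were higher and 2599 lower. The groups share no batch, and the NoRx.F arrays are from earlier days, 6 to 12. Regimen, day and batch therefore cannot be told apart.

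Against KY1005 alone, the combination at day 14 had a lower level of CXCR6, and the cell cycle list shifted down. The chemokine receptor CXCR6 fell by 3.07 ± 0.63, MMP8 by 2.99 ± 0.52 and the mitotic genes CENPA and TPX2 by 1.06 ± 0.26 and 1.03 ± 0.24 in 5 animals against 3, and SERPINB2 rose by 3.31 ± 0.68. The 28 cell cycle genes shifted down with 2 falls (10 adjusted over the list alone), with a median of -0.64 (adjusted p = 3.5e-10), and the 22 cytotoxic genes shifted down with none passing alone (2 adjusted over the list alone), with a median of -0.89 (adjusted p = 3.14e-05). Both had adjusted p = 0.345 with an estimated correlation. IFNG, the interferon-gamma gene, differed by -2.34 ± 0.68 (adjusted p = 0.0755). In all, 31 probe sets were higher and 84 lower, or 27% higher, against 55.4% after a further quantile normalization. The count of 115 was 0 in a fit of these groups alone, 660 without the 6 arrays of high actin ratio, 4 and 22 without the KY1005.F arrays of R.206 and R.211, and 400, 15, 288 and 42 without the combination arrays of R.218, R.219, R.220 and R.221. It was also higher with array weights and without a batch term, as given below. The KY1005.F arrays are from later days, 16 to 23.

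Against sirolimus alone, the combination at day 14 had lower levels of checkpoint genes. LAG3 fell by 1.87 ± 0.48, with ENTPD1 at -1.63 ± 0.39, TIGIT at -1.50 ± 0.35 and CXCR3 at -1.27 ± 0.30 in 5 animals against 4, while SERPINB2 rose by 3.99 ± 0.76 and RORA, a factor of Th17 cells, by 1.78 ± 0.47. Of 18 costimulation and checkpoint genes 3 fell (7 adjusted over the list alone; adjusted p = 0.000394, and adjusted p = 0.0953 with an estimated correlation). The cell cycle list shifted down with 2 falls among 28 (18 adjusted over the list alone), with a median of -0.90 (adjusted p = 1.81e-10, and adjusted p = 0.218 with an estimated correlation). The plasma cell genes MZB1 and JCHAIN fell by 0.95 ± 0.24 and 1.92 ± 0.51. TNFRSF4 differed by -0.83 ± 0.27 (adjusted p = 0.0909). In all, 162 probe sets were higher and 193 lower, 355 together. The groups share no batch, and the count was 712 without a batch term, 106 without the 6 arrays of high actin ratio, 611 and 17 without the Siro.F arrays of R.17 and R.18, and 663 and 41 without the combination arrays of R.218 and R.219.

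**Figure D4:**
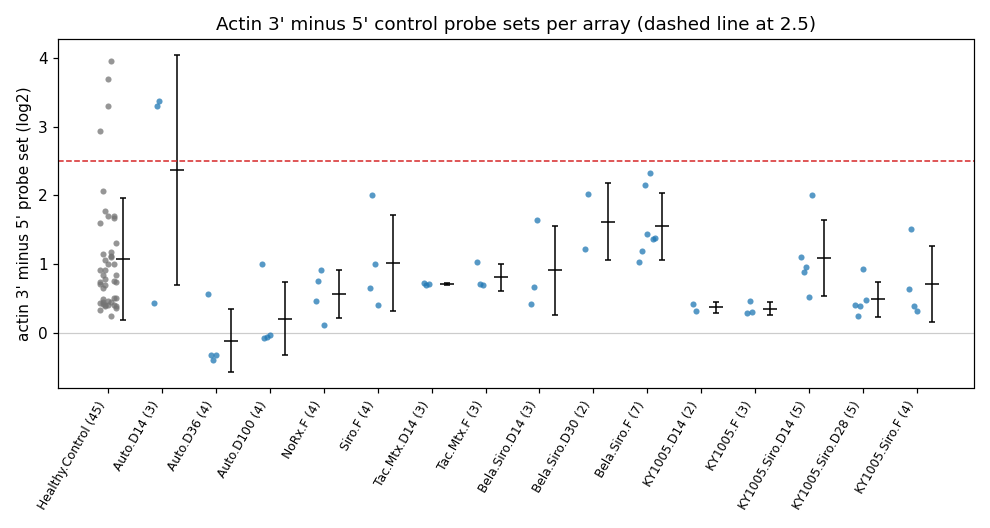
Log2 difference between the 3' and 5' actin control probe sets of each array by group, with mean and SD at the right of the points; a high value is a sign of shortened RNA. The dashed line at 2.5 lies between the 6 highest arrays, from 2.94 up, and the rest, up to 2.32.

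RNA quality, read from the 3' to 5' actin control probe sets, set 6 arrays apart: healthy controls R.22, R.32, R.207 and R.208 and the Auto.D14 arrays of R.201 and R.202. Their log2 ratios were 2.94 or more. The mean ratio was 2.37 ± 1.67 (SD, n = 3) in Auto.D14 and 1.08 ± 0.89 (SD, n = 45) in healthy controls. Of the 7 healthy arrays in the batch that holds every KY1005 group, R.207 and R.208 are 2.

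Against autologous recipients at the same day, the combination at day 14 had lower levels of division genes and higher levels of naive T cell genes in the main fit. No probe set passed without a batch term, and 2 of the 3 Auto.D14 arrays have a high actin ratio. CCNB2 fell by 2.41 ± 0.75, MKI67 by 2.01 ± 0.59, CXCR3 by 1.23 ± 0.35 and CD70, a costimulatory ligand, by 2.19 ± 0.51 in 5 animals against 3, and SERPINB2 rose by 3.99 ± 0.88, STAT3 by 2.31 ± 0.69 and SATB1 by 2.16 ± 0.56 (1 of its 4 probe sets passed in the other direction). Without a batch term these differences were smaller and none passed, with CD70 at -1.43, CXCR3 at -0.775, SERPINB2 at 2.67, STAT3 at 1.29 and SATB1 at 1.34. Without the 6 arrays of high actin ratio the difference of STAT3 was -0.02. SORL1, a naive and central memory gene that rose in the main fit, changed sign there too, as did CD6, KCNA3 and MKLN1. Of 28 cell cycle genes 6 fell (15 adjusted over the list alone), with a median of -0.87 (adjusted p = 0.000953, and adjusted p = 0.794 with an estimated correlation). Of 15 naive and central memory genes 5 rose (6 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.34 with an estimated correlation). In all, 1505 probe sets were higher and 1310 lower, or 53.5% higher, against 42.9% after a further quantile normalization. The groups share no batch, and the count of 2815 was 0 without a batch term, 5904, 1 and 0 without the Auto.D14 arrays of R.200, R.201 and R.202, 609 and 1822 without the combination arrays of R.219 and R.220, 0 without the 6 arrays of high actin ratio, and 340 with that ratio as a covariate.

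Few probe sets passed against the other prophylaxis groups at day 14 in the main fit, although both counts were higher with the actin ratio as a covariate. SERPINB2 rose by 4.94 ± 0.81 against tacrolimus with methotrexate and by 4.08 ± 0.81 against belatacept with sirolimus, in 5 animals against 3 each. Without a batch term, as the plain difference of the group means, these were 3.52 (adjusted p = 0.0481) and 2.66 (adjusted p = 0.636), and its means in the other groups, 2.92 and 3.78, are low. Against the former CCL20, a chemokine of mucosal tissue, rose by 1.76 ± 0.42, and TGFBR2, a receptor of TGF-beta, fell by 1.02 ± 0.21, but without a batch term these were 1.43 and -0.74 (adjusted p = 0.104 for both). There 24 probe sets were higher and 25 lower, or 49% higher, against 58.3% after a further quantile normalization, and none of 28 cell cycle genes passed (0 adjusted over the list alone), although the list shifted down with a median of -0.57 (adjusted p = 0.0098, and adjusted p = 0.709 with an estimated correlation). Against belatacept with sirolimus 15 were higher and 5 lower, and 154 and 48 after a further quantile normalization. There the interferon list shifted up with a median of 0.24 and no member past the threshold (0 adjusted over the list alone, list adjusted p = 0.0016, and adjusted p = 0.977 with an estimated correlation). MKI67 differed by -0.83 ± 0.55 (adjusted p = 0.423) and -0.12 ± 0.55 (adjusted p = 0.943). The combination shares no batch with either group, and without a batch term the counts of 49 and 20 were 4 and 3. The count of 49 ran over single arrays from 6 without the Tac.Mtx.D14 array of R.21 to 443 without the combination array of R.218. Other single arrays gave 207 and 21 (R.19 and R.20 of Tac.Mtx.D14) and 23, 8, 208 and 15 (R.217, R.219, R.220 and R.221 of the combination). The count of 20 was 3, 6 and 4 without the Bela.Siro.D14 arrays of R.38, R.42 and R.49 and 3, 243, 3, 63 and 5 without the combination arrays of R.217, R.218, R.219, R.220 and R.221.

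Near day 100, the combination differed from autologous recipients in cytotoxic and myeloid genes. TBX21 fell by 3.14 ± 0.67, S1PR5, a receptor of circulating effector cells, by 3.33 ± 0.74, GZMH by 2.87 ± 0.73 and GZMB by 2.04 ± 0.54 in 4 animals against 4. Of 22 cytotoxic genes 8 fell and none rose (14 fell and 1 rose adjusted over the list alone), with a median of -1.69 (adjusted p = 7.27e-06, and adjusted p = 0.218 with an estimated correlation). Of 14 monocyte and myeloid genes 9 rose (9 adjusted over the list alone), S100A9 by 5.46 ± 1.49, and of 8 granulocyte genes 5 rose (5 adjusted over the list alone), MMP9 by 3.78 ± 0.70. Both lists had adjusted p = 0.0981 with an estimated correlation. Of 28 interferon-induced genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), IFIT3 by 2.29 ± 0.62 (list adjusted p = 4.33e-05, and adjusted p = 0.322 with an estimated correlation). SATB1 rose by 1.81 ± 0.52, or 1.09 (adjusted p = 0.0961) without a batch term, and CD8A fell by 0.84 ± 0.23. In all, 1211 probe sets were higher and 1067 lower, or 53.2% higher, against 44.3% after a further quantile normalization. The groups share no batch, and the count of 2278 was 1104 without the 6 arrays of high actin ratio, 694 with the myeloid score as a covariate, 1181 without the Auto.D100 array of R.200, and 1281 and 1026 without the KY1005.Siro.F arrays of R.219 and R.220.

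From day 14 to near day 100 of the combination, genes of red cells and granulocytes rose. The hemoglobin gene HBA rose by 4.62 ± 1.15, ORM1, an acute phase protein, by 3.61 ± 0.55, SLC25A37 by 2.13 ± 0.39 and MMP9 by 2.82 ± 0.53 in 4 animals against 5, and SERPINB2 fell by 2.78 ± 0.62. Of 8 granulocyte genes 4 rose (5 adjusted over the list alone) and of 8 erythroid genes 2 rose (6 adjusted over the list alone), and both lists had adjusted p = 0.0517 with an estimated correlation. The 28 interferon-induced genes shifted up with none passing alone (16 adjusted over the list alone), with a median of 0.70 (adjusted p = 8.89e-11, and adjusted p = 0.126 with an estimated correlation). In all, 320 probe sets were higher and 76 lower, or 80.8% higher, against 63.1% after a further quantile normalization. The count of 396 was 668 with the animal as a random block. It was 0 with the animal as a fixed block, fitted on the KY1005.Siro arrays alone. A fit of only these groups, with no block, gave 0 too, so the 0 cannot be credited to the pairing. Without the day 14 arrays of R.219 and R.221 the count was 226 and 151, and without the later arrays of R.217 and R.219 it was 968 and 28.

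The change over time was also set against that of autologous recipients, from Auto.D14 to Auto.D100. No probe set passed in limma, and 3268 had an unadjusted p under 0.05, with 3171 passing under array weights and 52 with the animal as a random block. Interferon-induced genes shifted up more in the combination, by a median of 1.16 (none of 28 passing, 12 higher adjusted over the list alone; adjusted p = 1.75e-10, and adjusted p = 0.207 with an estimated correlation). At the start of this time course the Auto.D14 arrays of R.201 and R.202, 2 of 3, have a high actin ratio, and without the 6 such arrays the median was 0.87. The count was 493 without the Auto.D14 array of R.200, 388 and 24 without the KY1005.Siro.F arrays of R.217 and R.220, and 16 without the day 14 array of R.221.

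The OX40 gene TNFRSF4 had a mean log2 value of 7.72 ± 0.29 (SD, n = 45) in healthy controls, 8.52 ± 0.27 (SD, n = 4) in NoRx.F, 8.98 ± 0.58 (SD, n = 4) in Siro.F, 8.06 ± 0.23 (SD, n = 3) in KY1005.F and 8.31 ± 0.51 (SD, n = 5) in KY1005.Siro.D14. It rose in NoRx.F by 0.75 ± 0.19 and in Siro.F by 1.22 ± 0.18. Compared directly, KY1005.F differed from NoRx.F by -0.60 ± 0.30 (adjusted p = 0.193). KY1005.Siro.D14 differed from Siro.F by -0.83 ± 0.27 (adjusted p = 0.0909), so neither difference between regimens passed. In KY1005.Siro.D14, KY1005.Siro.D28 and KY1005.Siro.F the value of TNFRSF4 differed from healthy controls by 0.40 ± 0.19 (adjusted p = 0.243), 0.28 ± 0.19 (adjusted p = 0.36) and 0.05 ± 0.20 (adjusted p = 0.914). CD4 passed in none of the 15 main comparisons, nor did FOXP3. CCR7, a receptor that guides T cells to lymph nodes, fell in NoRx.F by 1.28 ± 0.37 and passed in no other main comparison. MKI67 rose against healthy controls by 3.30 ± 0.37 in NoRx.F, 1.58 ± 0.36 in Siro.F and 1.44 ± 0.43 in KY1005.F. IFNG passed in Siro.F alone, at 1.56 ± 0.52. CD8A rose in NoRx.F by 0.73 ± 0.16, and its difference between KY1005.Siro.D14 and NoRx.F was -0.999 ± 0.22.

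Results of other gene lists were as follows. Of 10 measured Th2 genes 2 rose and 3 fell in NoRx.F (2 and 3 adjusted over the list alone; adjusted p = 0.779), where the median of -0.04 and the mean of 0.04 differ in sign and the test pointed down. Of 8 NK cell genes 1 rose and 2 fell there (1 and 3 adjusted over the list alone; adjusted p = 0.299). Neither list was called in any of the 30 comparisons or in the difference of time courses. Against healthy controls the 12 mTORC1 target genes shifted up in KY1005.F, with none passing alone (0 adjusted over the list alone; adjusted p = 0.00716, and adjusted p = 0.135 with an estimated correlation). In KY1005.Siro.D14, 2 of 12 Th17 genes rose (2 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.232 with an estimated correlation) and 2 of 8 core T cell genes fell (3 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.192 with an estimated correlation). Against KY1005.F the same group had 1 fall among 11 Th1 genes (3 adjusted over the list alone) and 1 among 16 tissue homing genes (4 adjusted over the list alone), with adjusted p = 0.345 and adjusted p = 0.362 with an estimated correlation, and none of 6 heat shock genes passed (0 adjusted over the list alone; adjusted p = 0.0437, and adjusted p = 0.358 with an estimated correlation), where the median of -0.50 was 0.03 without the KY1005.F array of R.211. Against Siro.F none of its 8 B cell genes passed (3 lower adjusted over the list alone; adjusted p = 0.0408, and adjusted p = 0.337 with an estimated correlation). The 20 sterol and lipid synthesis genes shifted down in KY1005.Siro.F against Auto.D100, with 2 falls (4 adjusted over the list alone; adjusted p = 0.00282, and adjusted p = 0.171 with an estimated correlation). The 9 platelet genes shifted up in KY1005.Siro.F against healthy controls, with none passing alone (0 adjusted over the list alone; adjusted p = 0.0252, and adjusted p = 0.554 with an estimated correlation).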

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

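The weighing of explanations and the count of other splits of the arrays in this part are tests chosen only after the results were seen.

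Arrays far from the rest of their group were found in 13 of 120 tests, where chance gives about 1 in 20, or 6. In KY1005.Siro.D28 the array of R.219 had a cell cycle score of 0.50 (others -0.26 to -0.06), an MKI67 value of 6.99 (others 5.62 to 6.00) and a myeloid score of -0.87 (others 0.65 to 1.08). The cell cycle score of R.217 in KY1005.Siro.F was 0.51 (others -0.34 to -0.21). In NoRx.F the cytotoxic score of R.53 was 0.77 (others 0.12 to 0.22), the interferon score of R.52 was 1.66 (others 0.63 to 0.77), and R.51 had an erythroid score of 0.41 (others 0.12 to 0.17) and a FOXP3 value of 5.57 (others 4.78 to 4.91). In Siro.F the granulocyte score of R.13 was 0.72 (others -0.01 to 0.06) and the CD8A value of R.17 was 11.6 (others 12.8 to 13). In Auto.D100 the OX40 and NF-kB score of R.202 was -0.0525 (others 0.06 to 0.09), the FOXP3 value of R.201 was 5.33 (others 5.21 to 5.22) and the CD4 value of R.60 was 7.05 (others 7.36 to 7.40).

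The change from day 14 to near day 100 differed between KY1005 with sirolimus and autologous recipients for 6 lists. The differences in median log2 were 1.16 for interferon response (adjusted p = 1.75e-10), 1.29 for monocyte and myeloid genes (adjusted p = 0.000283), 1.72 for granulocyte genes (adjusted p = 4.57e-05), 1.14 for erythroid genes (adjusted p = 0.000784), 0.75 for platelet genes (adjusted p = 0.00265) and -0.61 for cytotoxic genes (adjusted p = 0.00517). None held with an estimated correlation (adjusted p = 0.207 for interferon response and granulocyte genes, adjusted p = 0.384 for erythroid, adjusted p = 0.477 for myeloid and platelet, and adjusted p = 0.798 for cytotoxic genes). Of the 3 Auto.D14 arrays, R.201 and R.202 have high actin ratios of 3.30 and 3.38. Without the 6 arrays of high ratio the median difference was -0.28 for cytotoxic genes (adjusted p = 0.764) and 0.87, 1.40, 1.70, 1.38 and 0.40 for interferon, myeloid, granulocyte, erythroid and platelet genes. Without the Auto.D14 array of R.201 that of cytotoxic genes was -0.45 (adjusted p = 0.118) and without the KY1005.Siro.F array of R.220 it was -0.58 (adjusted p = 0.0578). Without the KY1005.Siro.F array of R.219 the myeloid difference was 0.40 (adjusted p = 0.151) and the granulocyte difference 0.47 (adjusted p = 0.0162).

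Control probe sets outside the comparisons gave a mean log2 actin ratio of 2.37 in Auto.D14, against 1.08 in healthy controls, whose highest array had 3.95. RNA quality is a candidate explanation for the probe sets called between KY1005.Siro.D14 and Auto.D14. Over them the arrays of R.202 and R.201, with ratios of 3.38 and 3.30, differed from KY1005.Siro.D14 by a median of 1.24 and 1.20, and R.200, with 0.44, by 0.74, or 60.5% of the mean of the others. That share is above the bound of 50% set against the explanation, but it rests on a single array and excludes nothing. R.200 was also among the arrays by which these probe sets were called. The healthy arrays of R.208 and R.207, with ratios of 3.95 and 3.3, differed in the same direction by 0.896 and 0.859. Those of R.22 and R.32, with 3.69 and 2.94, differed by 0.292 and 0.318. RNA quality and the group cannot be told apart, since only R.200 has a usual ratio, and a biological difference between the regimens stays open, untested.

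Markers of monocytes, granulocytes and red cells in KY1005.Siro.F may come from RNA of other cells, although the sort for CD3 would remove them. Of the 22 listed genes 21 (95.5%) lay above healthy controls, which restates the rise of the lists and decides nothing, and of the listed genes CD68 differed by -0.45 (adjusted p = 0.515). The test was therefore made on 14 further genes of monocytes and granulocytes, outside the lists and not looked at before, of which 13 (92.9%) lay above healthy controls and 6 passed (p = 2.61e-11, and p = 0.00323 with an estimated correlation), with CYBB at 2.22 ± 0.65. The array of R.219 alone does not account for the rise of the myeloid list: without it the median was 1.12 (adjusted p = 1.82e-07) in place of 2.11, above the SD of 0.51 of the healthy scores. The medians of the granulocyte and erythroid lists without it were 0.68 (adjusted p = 0.000227) in place of 1.96, and 1.46 (adjusted p = 1.52e-08) in place of 1.04. These use the preset correlation, and with an estimated one over all arrays the erythroid list was not called (adjusted p = 0.099) and the myeloid and granulocyte lists were (adjusted p = 0.028 for both). A change of expression in the T cells themselves could give such rises too and stays open.

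The KY1005.F array of R.206 lay close to the arrays of R.212, with r = 0.991 over probe sets to the day 16 array and r = 0.990 to the KY1005.F array, where the highest value between groups for arrays of the same animal was 0.988 and the next for different animals 0.989. A mislabelled sample is a candidate source. At 72 probe sets with separate high and low states, R.206 matched the day 16 array of R.212 at 91.7% and its own healthy array at 75%. Arrays of the same animal matched at a median of 81.9% and different animals at 59.7%, at most 95.8%. These cannot be told apart, since 11 pairs of different animals (0.216% of them) matched as well and T cells after transplant can come from a donor. Of the 5 versions of this test, the others gave matches to the day 16 array of 95.8%, 83.7%, 87% and 91.7% and to the own healthy array of 91.7%, 59.2%, 56.5% and 50%, where the medians of different animals were 64.6%, 59.2%, 56.5% and 58.3%.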

How the results depend on the processing

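The tests chosen only after the result was seen are those that leave out the 6 arrays of high actin ratio, with or without restriction to the batch, and those with the actin ratio or the myeloid score as a covariate.

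Over 26 gene lists and the genes of the naming rule, most values under alternatives held, but most list calls were lost with an estimated correlation. There 188 of 197 list results lost the threshold and 9 held. Genes called in neither setting, with the same sign, count among those kept. Of 15806 values of 744 gene results under alternatives 13105 kept direction and side of the threshold, 2562 kept direction and lost the threshold, 45 passed it, 80 moved and 14 reversed. Of 3892 values of 197 list results 3338 held, 552 lost the threshold and 2 reversed. No called probe set of the 15 main comparisons changed sign under a further quantile normalization. A trended robust prior moved no count of a main comparison over 1.5 times. The cause was not tested for any change below, except that a 2-fold minimum adds a condition and fewer arrays leave less to test with.

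With a 2-fold minimum the counts against healthy controls were 2001 for NoRx.F, 574 for Siro.F, 390 for KY1005.F, 272 for KY1005.Siro.D14, 896 for KY1005.Siro.D28 and 899 for KY1005.Siro.F. They were 1225 for KY1005.F and 1956 for KY1005.Siro.D14 against NoRx.F, 70 for the latter against KY1005.F, 214 against Siro.F, 1555 against Auto.D14, and for KY1005.Siro.F 1410 against Auto.D100 and 224 against KY1005.Siro.D14.

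Within the batches that hold the group the counts against healthy controls were 1614 for Siro.F, 6 for KY1005.F, 53 for KY1005.Siro.D14, 620 for KY1005.Siro.D28 and 16 for KY1005.Siro.F, and without the arrays of high actin ratio 1350, 195, 181, 1632 and 21. Without a batch term they were 2367 for KY1005.F and 2195 for KY1005.Siro.D14, 4935 for KY1005.F against NoRx.F, and for KY1005.Siro.D14 230 against KY1005.F, 712 against Siro.F, 0 against Auto.D14, 4 against Tac.Mtx.D14 and 3 against Bela.Siro.D14, and 9 for the difference of time courses.

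Without the 6 arrays of high actin ratio the counts were 145 for KY1005.F, 725 for KY1005.Siro.D28 and 756 for KY1005.Siro.F against healthy controls, 1212 for KY1005.F against NoRx.F, and for KY1005.Siro.D14 660 against KY1005.F, 106 against Siro.F, 0 against Auto.D14, 23 against Tac.Mtx.D14 and 5 against Bela.Siro.D14. For KY1005.Siro.F they were 1104 against Auto.D100 and 609 against KY1005.Siro.D14. With the ratio as a covariate they were 239 for KY1005.F and 2350 for KY1005.Siro.D28 against healthy controls, 72, 600, 340, 300 and 126 for KY1005.Siro.D14 against KY1005.F, Siro.F, Auto.D14, Tac.Mtx.D14 and Bela.Siro.D14, and 3 for the difference of time courses. With the myeloid score as a covariate they were 427 for KY1005.Siro.D14 and 383 for KY1005.Siro.F against healthy controls, 34 for KY1005.Siro.D14 against Bela.Siro.D14 and 694 for KY1005.Siro.F against Auto.D100.

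Array weights gave 8253 for KY1005.F against healthy controls, 7349, 6385, 85 and 6 for KY1005.Siro.D14 against KY1005.F, Auto.D14, Tac.Mtx.D14 and Bela.Siro.D14, 4921 for KY1005.Siro.F against Auto.D100 and 3171 for the difference of time courses. A fit of only the groups compared gave 1367 for KY1005.Siro.F against healthy controls, 1754 for KY1005.F against NoRx.F, 0 and 1217 for KY1005.Siro.D14 against KY1005.F and Auto.D14, and 0 for KY1005.Siro.F against KY1005.Siro.D14. No filter gave 681 for KY1005.F against healthy controls, and 1650 and 30 for KY1005.Siro.D14 against Auto.D14 and Tac.Mtx.D14. The stricter filter gave 8 and 0 for KY1005.Siro.D14 against Tac.Mtx.D14 and Bela.Siro.D14 and 227 for KY1005.Siro.F against KY1005.Siro.D14. A further quantile normalization gave 611, 96 and 202 for KY1005.Siro.D14 against Siro.F, Tac.Mtx.D14 and Bela.Siro.D14. The 4 KY1005-only animals together gave 1607 against healthy controls. With the animal as a random block, the counts were 668 for KY1005.Siro.F against KY1005.Siro.D14 and 52 for the difference of time courses. A fixed block, on the KY1005.Siro arrays alone, gave 0 for the former, as did the fit of only these groups without a block. The block moved no other main count by over 1.5 times.

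Leaving out each array in turn gave 1016 to 2647 for Siro.F, 41 to 1008 for KY1005.F, 658 to 1671 for KY1005.Siro.D14, 1782 to 3864 for KY1005.Siro.D28 and 483 to 3275 for KY1005.Siro.F against healthy controls, and 1087 to 3729 for KY1005.F against NoRx.F. For KY1005.Siro.D14 it gave 4 to 400 against KY1005.F, 17 to 663 against Siro.F, 0 to 5904 against Auto.D14, 6 to 443 against Tac.Mtx.D14 and 3 to 243 against Bela.Siro.D14. For KY1005.Siro.F it gave 1026 to 3414 against Auto.D100 and 28 to 968 against KY1005.Siro.D14, and 0 to 493 for the difference of time courses. For part of these counts the arrays are named with the comparisons above.

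As the mean of all probe sets of a gene, NDUFS6 was -0.39 in NoRx.F and -0.042 in KY1005.Siro.D14 against healthy controls and 0.22 in KY1005.F against NoRx.F, IRF7 0.12 in KY1005.Siro.D14 against healthy controls, OAS1 -0.39 in KY1005.Siro.D14 against NoRx.F, METTL18 -0.012 against KY1005.F, and HK1 0.17 and NDUFB6 0.12 against Auto.D14, each opposite to its called sign. Without the 6 arrays of high actin ratio CD6 was -0.16, KCNA3 -0.043, MKLN1 -0.25, SORL1 -0.33 and STAT3 -0.02 against Auto.D14, where each had risen. With the myeloid score LOC715741 was -0.29 in KY1005.Siro.F against Auto.D100. Leaving out each array in turn, the median of the heat shock list of KY1005.Siro.D14 against KY1005.F ran from -0.903 to 0.03, reversed without the KY1005.F array of R.211. That of the erythroid list of Tac.Mtx.D14 against healthy controls ran from -0.089, reversed without R.21, to 1.358.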

Other observations

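The list of STAT5 targets and the splits of the arrays are tests chosen only after the results were seen.

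Cell cycle genes rose in groups outside the main comparisons as well. Against healthy controls 22 of 28 rose in Auto.D36 (22 rose and 2 fell adjusted over the list alone), with a median of 1.10 (adjusted p = 5.94e-19, and adjusted p = 0.132 with an estimated correlation), and 17 in Tac.Mtx.F (22 adjusted over the list alone), with a median of 0.96 (adjusted p = 1.85e-09, and adjusted p = 0.196 with an estimated correlation). In Bela.Siro.F 12 of 22 cytotoxic genes fell (15 adjusted over the list alone), with a median of -0.92 (adjusted p = 1.8e-08, and adjusted p = 0.294 with an estimated correlation). Siro.F against NoRx.F had 12 falls among 28 cell cycle genes (16 adjusted over the list alone), with a median of -0.92 (adjusted p = 4.16e-10, and adjusted p = 0.423 with an estimated correlation). KY1005.Siro.F against Bela.Siro.F had 5 rises among 28 interferon-induced genes (6 adjusted over the list alone, list adjusted p = 2.49e-08, and adjusted p = 0.269 with an estimated correlation). KY1005.Siro.F and Bela.Siro.F share no batch, and their arrays are from days 97 to 106 and days 26 to 105. Regimen, day and batch therefore cannot be told apart there.

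SOCS2, SOCS3 and BCL2, targets of the cytokine-activated factor STAT5, were among the rises of KY1005 with sirolimus, so higher STAT5 activity is a candidate explanation. A list of further targets was tested, of which LIF, OSM, PIM1 and SOCS1 were measured and had not been looked at. Their median rose by 0.33 at day 14 (0.326; 1 of 4 passing; adjusted p = 0.0019), by 0.27 at day 28 (adjusted p = 0.00315) and by 0.84 near day 100 (adjusted p = 0.00129), and with an estimated correlation adjusted p = 0.00299, adjusted p = 0.0043 and adjusted p = 0.00235. The shift was not confined to the combination: the medians were 0.44 in KY1005.F (adjusted p = 0.00315), 0.64 in Siro.F (adjusted p = 0.0325) and 0.06 in NoRx.F (adjusted p = 0.976), and differences between groups were not tested. Myeloid cells are another possible source, since they can express OSM and PIM1 and S100A9 rose by 3.55 at day 14 and 4.41 near day 100. With the myeloid score as a covariate the medians were 0.32 at day 14 (adjusted p = 0.00381), 0.29 at day 28 (adjusted p = 0.00574) and 0.46 near day 100 (adjusted p = 0.00171), so the shift stayed past the threshold, and RNA of other cells stays open as part of it. A first version of the list held 7 genes, of which BCL2L1, CISH and MYC had in fact been looked at before, and gave 0.33 at day 14 (adjusted p = 0.000143). With 4 genes, of which 1 passed at day 14 and at day 28 and 2 near day 100, the test shows a shift of a small set and says nothing of STAT5 protein.

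Chance as the source of the counts was tested by other splits of the same arrays. As many probe sets as the real split were called in 1 of 100 splits for NoRx.F against healthy controls (8705, highest other 259) and for Siro.F (2824, highest other 331), and in 2 of 100 for KY1005.F (1040, highest other 10849), KY1005.Siro.D14 (1315, highest other 4762), KY1005.Siro.D28 (3838, highest other 5261) and KY1005.Siro.F (2170, highest other 7011), the real split included. For the KY1005 groups the highest other split put the healthy arrays of R.207 and R.208, of high actin ratio, together, which points to a structure of the samples; the counts within the batch without such arrays were 195, 181, 1632 and 21. The real split was the highest of 35 for KY1005.F against NoRx.F (2772, highest other 2770) and for KY1005.Siro.F against Auto.D100 (2278, highest other 636), and of 100 for KY1005.Siro.D14 against NoRx.F (4938, highest other 3148) and Siro.F (355, highest other 315). For KY1005.Siro.D14, 2 of 56 splits gave as many against KY1005.F (115, highest other 449), Auto.D14 (2815, highest other 6356) and Tac.Mtx.D14 (49, highest other 366). The split with 6356 differs from the real one by an exchange of R.200, with an actin ratio of 0.44, and R.221, with 2. It thus parts the arrays of highest ratio, R.202 (3.38), R.201 (3.3) and R.221, from the rest, up to 1.10. It parts most of the regimens too, but called more probe sets than the real split. Without the 6 arrays of high actin ratio the count was 0. In each of the tests so far under 1 in 20 splits called as many, with no adjustment for the number of tests. Other splits called more than the real one for the KY1005 groups against healthy controls and for KY1005.Siro.D14 against KY1005.F, Auto.D14 and Tac.Mtx.D14. Where groups differ in batch or RNA quality, the splits exchange arrays across these too. The shares therefore do not exclude chance and say nothing about batch. For KY1005.F against NoRx.F the split with 2770 set the NoRx.F arrays of batch 1 (R.50, R.51 and R.52) against the rest, so it parts batch 1 from the others but also most of the regimens, as only R.53 moved. These groups share no batch, so their difference and a batch difference cannot be told apart, and without a batch term the count was 4935. Against Bela.Siro.D14 the share was not under 1 in 20, as 3 of 56 splits gave as many (20, highest other 151). For the difference of time courses limma called 0 probe sets (3268 with an unadjusted p under 0.05), so all 100 splits gave as many by necessity (highest other 2327) and the splits decide nothing. For KY1005.Siro.F against KY1005.Siro.D14, 4 of 100 splits gave as many (396, highest other 931), and among the 16 that part the 4 pairs of arrays of the same animal 3 did, which are too few splits for a share under 0.05. The highest swapped the arrays of R.217. With the animal as a fixed block, on the KY1005.Siro arrays alone, the count was 0, as it was in a fit of only these groups without a block.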
